A study of Mus musculus with 26 samples.

How the data were processed

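Gene expression was measured on 26 mouse arrays with 2 channels each that together held 26 RNA samples from 13 groups of mice, 2 samples per group. Each RNA sample was hybridised on 2 arrays, once in each channel, so that the arrays closed into a single loop with no common reference. The groups were the wild type strains bl6 and bl10, the dystrophin-deficient lines mdx and mdx3cv, the sarcoglycan-deficient lines sgca, sgcb, sgcb2, sgcd and 1 more, which is part of the pooled lines and whose own results are not reported here, the dysferlin-deficient lines dysf and sjl, the sarcospan-deficient line sspn, and hDMD, a line that carries the human DMD gene. The relation of sgcb2 to sgcb was taken from its name alone. The tissue, the age and sex of the mice, the background strain of the lines, the dyes, the scanner and the normalization were not given in the sources used here. Background strain is therefore not separated from the missing protein in any comparison that holds a line. The labels do not say that the 2 samples of a group came from separate mice, so the p-values measure only the spread between these samples, which may be technical.

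Per the labels, each array was deposited as 1 value per spot, and no unit or direction of the ratio was stated. The design had assumed deposited log2 ratios, but the deposited values were ratios on a natural log scale. Whole-number scanner intensities leave a lattice of repeated values. On 4 arrays a chain of at least 7 recurring steps could be followed, and its scale was a whole multiple of the natural log unit on 4 of these within a tolerance of 1%, of the log2 unit on 0 and of the log10 unit on 0. The remaining arrays held no such chain and were taken to share the unit. The search for chains assumed a generalized logarithm, which would understate the change of dim spots, and did not set it against a plain logarithm. The deposited values were divided by 0.6931 to give log2 ratios. No other background correction or normalization was applied to the ratios as deposited by the authors. The deposited medians of the arrays lay between -0.074 and 0.173 on the natural log scale, so the centring of the deposited values stays unknown.

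The table had 16416 rows of spots and 0 missing values. Of these rows, 13662 were paired with 1 gene, 14 with several genes and 2740 with none, and 13602 matched the reference gene table by Entrez identifier, which updated 0 symbols. Rows of 1 gene were averaged, which gave 6540 genes. Of these, 6370 genes were on 2 rows and 170 were on more, including Gapdh on 160 rows. For the 20 genes named in the largest comparison, 0 rows had the opposite sign to the mean of their gene.

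The direction of the ratio was decided from the genes that the lines lack, by a rule fixed before the data were examined. The table measured 6 such genes in 9 pairs of gene and line. With channel 1 over channel 2, 7 of the 9 pairs were lower in their own line, 3 of them with an unadjusted p under 0.05. With channel 2 over channel 1, 2 of the 9 were lower and 0 of these had such a p. Channel 1 over channel 2 was therefore taken as likely, and every direction printed rests on it.

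The log2 ratios were fitted by generalized least squares with 1 dye term and 12 group terms (13 design columns). Each RNA sample was a random effect, with 1 variance ratio of 0.207 estimated by REML over all genes. This left 13 residual degrees of freedom. limma's empirical Bayes test added 7.38 prior degrees of freedom, for 20.4 in total, and p-values were adjusted by Benjamini-Hochberg over the 6540 genes with a threshold of 0.05. The comparison named DS set the mean of the 7 dystrophin- or sarcoglycan-deficient lines (14 samples) against the mean of both wild type strains (4 samples). In all, 19 comparisons were run. A second correction over the members of a gene list is called adjusted over the list alone.

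Before the data were examined, 37 gene lists were written. Those with at least 4 measured members, 36 lists, were tested with limma's camera on the whitened values, with the preset correlation of 0.01 between genes and again with an estimated correlation, and adjusted by Benjamini-Hochberg over the lists of a comparison. The histocompatibility list had 2 measured members and was left out. Named genes are the 10 largest log2 differences in each direction past the threshold in the DS and dysferlin comparisons, the 4 largest in each direction elsewhere, the genes that the lines lack, and up to 4 members of each list with the smallest p. Predicted or clone symbols were counted and passed over. Some genes outside this rule, among them clock genes, bone and marrow genes and further members of the lists, were named after their values were seen.

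The fit was tested on simulated data for the comparison of DS with wild type, with 6540 genes, 5 simulated sets and 200 changed genes per set. It recovered 7.16% of genes changed 1.5-fold (24 of 335), 49.3% of those changed 2-fold (165 of 335) and 93.6% of those changed 4-fold (309 of 330). Of 524 calls, 26 were false (4.96%). The random draws depend on the order of the genes. With the genes in byte order the same test recovered 7.46%, 49.9% and 93.6%, and 17 of 518 calls were false (3.28%). Both orders had been run when the first was kept. The simulated genes were drawn independently of one another, each with the same spread on all arrays. Real genes are correlated and the real arrays differed in spread, so these rates may not hold for the real data.

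Arrays have no read depth, and their number limits the precision. The SD of the log2 ratios of an array ranged from 0.46 to 1.3, and the correlation between duplicate spots ranged from 0.38 to 0.943 with a median of 0.744. Arrays that shared an RNA sample in opposite channels had correlations across genes from -0.831 to 0.471. The alternatives covered the error structure, the dye term, the replicate numbers, centring and scaling, the filter, row averaging, the prior, the choice of wild type strain, the lines in the pools and each RNA sample left out in turn. Array weights and centring in blocks of rows were added after the data were seen. limma's REML array weights stopped before they converged, and the gene-by-gene form replaced them after that result was seen. It depends on the order of the genes (677 genes in DS against wild type, and 673 in byte order). Analyses used R 4.3.3, limma 3.58.1, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.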

Results

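The series compared mouse lines that lack dystrophin, a sarcoglycan, dysferlin or sarcospan with wild type mice of the bl6 and bl10 strains and with a line carrying the human DMD gene. Dystrophin links the cytoskeleton of muscle fibres to a membrane complex that holds the sarcoglycans and sarcospan, and dysferlin takes part in the repair of the fibre membrane. Each of the 13 groups had 2 RNA samples, and each sample was on 2 of the 26 arrays. The arrays measured 6540 named genes. The median residual SD was 0.49 on the log2 scale. The signs of all values below rest on channel 1 over channel 2, which is likely because 7 of 9 pairs of a missing gene and its line were lower under it, against 2 of 9 under the other direction.

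The gene that each line lacks was examined first. These same genes had set the direction of the ratios, so only the size of a difference, and not its sign, bears on the labels. Sgca, which encodes alpha-sarcoglycan, fell by 4.33 ± 0.49 (SE, n = 2) on the log2 scale in the sgca line (limma with Benjamini-Hochberg, adjusted p = 6.98e-05; adjusted over the list alone, 1.92e-07), and was lower in sgca on 4 of its 4 arrays, by -5.39 to -2.55. Sspn, the sarcospan gene, differed by -1.21 ± 0.40 in sspn, on 4 of 4 arrays, which passed limma's test when adjusted over the list alone (0.0311) but not over all genes (adjusted p = 0.253). Sgcb, the gene of beta-sarcoglycan, differed by -1.25 ± 0.63 in sgcb and -1.01 ± 0.55 in sgcb2, lower on 8 of 8 arrays, with limma adjusted p = 0.452 and 0.635. Dmd, the dystrophin gene, differed by -0.68 ± 0.31 in mdx and -0.46 ± 0.33 in mdx3cv (adjusted p = 0.337 and 0.683 by limma), and was lower on 3 of 6 arrays. Sgcd, the gene of delta-sarcoglycan, differed by -0.30 ± 0.45 in sgcd (limma adjusted p = 0.859), and on 4 of 4 arrays it was lower by at most -0.54. Dysf, the dysferlin gene, was not lower in the dysferlin-deficient lines, at 0.55 ± 0.62 in dysf and 0.76 ± 0.50 in sjl (limma adjusted p = 0.82 and 0.729), and was lower on 2 of 8 arrays. Where the spots of a gene lie within its transcript was not given in the sources used here, so a spot outside a changed part would check nothing.

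**Figure D1:**
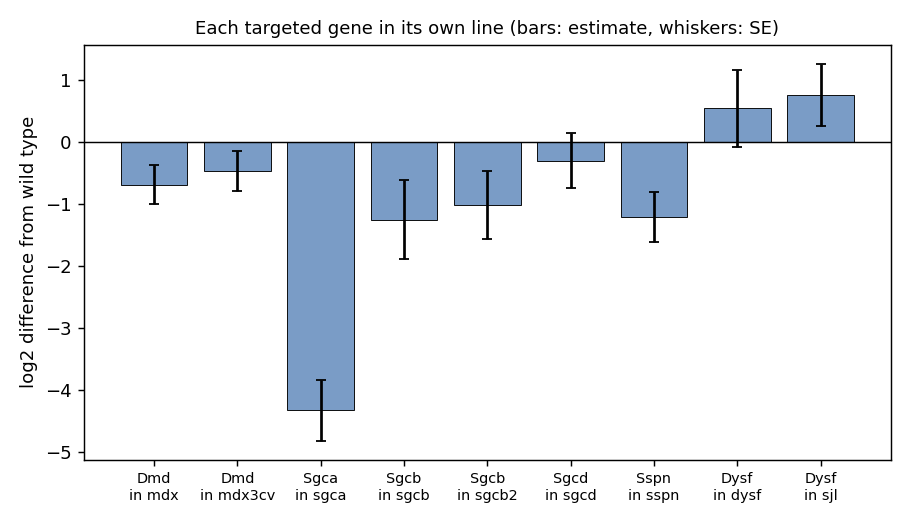
Log2 difference from wild type (y axis) of each missing gene in its own line (x axis), with bars for the limma estimate and whiskers for 1 SE. Sgca in the sgca line stands apart at -4.33, and both bars of Dysf lie above 0.

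The main question was which genes the dystrophin- and sarcoglycan-deficient lines, called DS lines here, shared in their difference from wild type. Genes of macrophages were among those that rose most. Clec7a, a receptor for fungal glucans on macrophages, rose 17.1-fold (log2 4.10 ± 0.49, limma adjusted p = 0.000178, higher in 7 of 7 lines). Lgals3, which encodes galectin-3, a marker of activated macrophages, rose by 3.72 ± 0.70 on the log2 scale (limma adjusted p = 0.00367, 7 of 7 lines). The pore-forming protein gene Mpeg1 rose by 3.11, the lysosomal protease gene Ctss by 3.06, the chemokine gene Ccl2, which draws monocytes, by 3.04 and Ly86, which encodes a partner of a toll-like receptor, by 3.02, each in 7 of 7 lines. S100a9, a calcium-binding protein gene of neutrophils and monocytes, rose by 3.44 ± 0.37, but from 0.14 to 6.49 between lines.

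Genes active in developing and regenerating muscle formed another part of the rise. The imprinted genes Mest and H19, which are abundant in embryonic tissue, rose by 3.08 ± 0.46 and 3.07 ± 0.52, and Tnni1, the troponin I of slow fibres, by 3.24 ± 0.56 (limma adjusted p = 0.00119, 0.0023 and 0.00247), each in 7 of 7 lines. The largest fall was that of Cish, a suppressor of cytokine signalling, at -2.84 ± 0.51 (limma adjusted p = 0.00296). Arntl, a core gene of the circadian clock, fell by 1.64 ± 0.25 (limma adjusted p = 0.00125), and Per2, another clock gene, was 1.32 higher (limma adjusted p = 0.0261; chosen after its value was seen). Inmt (-2.02), Eya4 (-1.70), a transcriptional coactivator, Kat6b (-1.69), a histone acetyltransferase, Sec1 (-1.67), Tshb (-1.67), Fgf4 (-1.62) and Timp4 (-1.61), an inhibitor of matrix metalloproteases, fell in 7 of 7 lines each. Asb2 (-1.68), part of a ubiquitin ligase, fell in the pool but was lower in 6 of 7 lines.

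By limma with Benjamini-Hochberg, 422 genes were higher and 88 lower in the DS lines (14 samples) than in wild type (4 samples), and 357 of these 510 differed by over 2-fold. The direction was the same in 7 of 7 lines for 489 of the 510 genes (95.9%), against 1901 of the 6030 genes that did not pass (31.5%). The 510 genes were chosen by the mean of these same 7 lines, which all share the wild type samples. Agreement in direction is therefore largely built in, also where lines are counted for single genes. After centring and scaling the arrays alike the split was 126 higher and 54 lower (70% higher, against 82.7%). The count rested on the choice of wild type strain, with 455 genes against bl6 alone and 10 against bl10 alone, all 10 among the 510. It also rested on single samples, with 74 genes without bl6 sample 1, 93 without bl10 sample 2, 103 without mdx sample 1, 198 without mdx3cv sample 2, 211 without bl10 sample 1, 227 and 294 without sgcb2 samples 1 and 2, 274 without sgcd sample 1 and 279 without sgca sample 1.

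**Figure D2:**
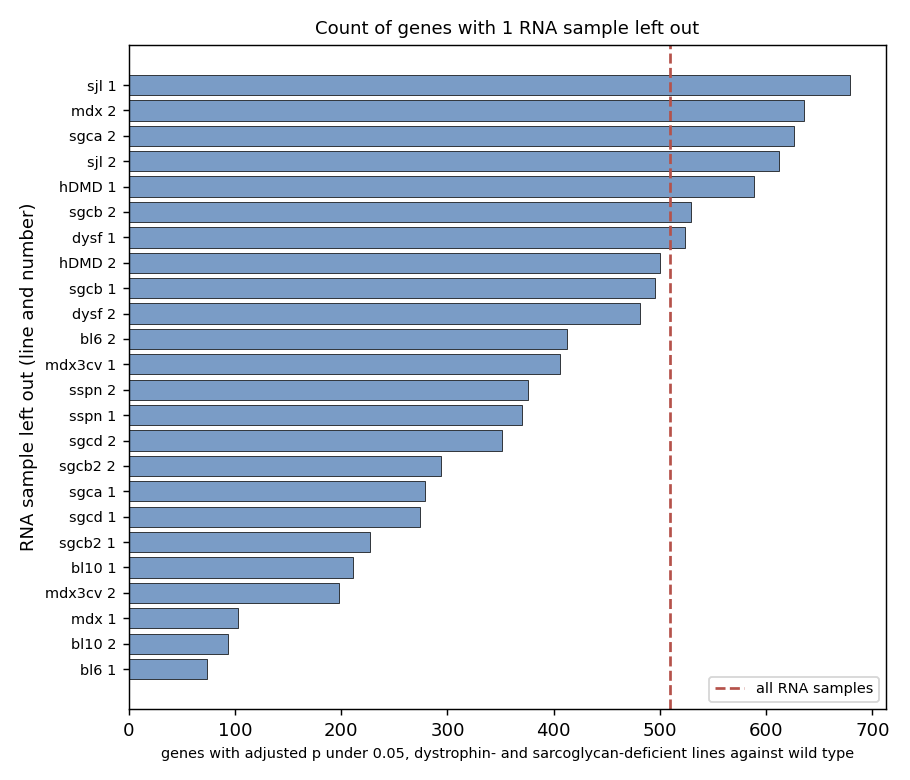
Number of genes with adjusted p under 0.05 in the DS lines against wild type (x axis) when 1 RNA sample is left out (y axis), for 24 of the 26 samples. The count runs from 74 without bl6 sample 1 to 679 without sjl sample 1, around 510 with all samples.

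Of the 36 lists tested with limma's camera, 12 were higher and 3 lower in the DS lines. All 15 calls were lost with an estimated correlation between genes, so each list is given with that adjusted p. The macrophage list had 22 of 41 members higher and 1 lower (adjusted over the list alone, 29 and 2), with a mean of 1.62 and means above 0 in 7 of 7 lines (adjusted p = 1.86e-13; adjusted p = 0.181 with an estimated correlation). Beyond the genes above it held Ptprc, the common leukocyte antigen (2.85), and Cd52 (3.00). It was less raised on the arrays against bl10 (0.62, 0.62 and 0.64) than on those against bl6 (3.72 and 2.96), which carried other DS lines. Of the chemokines and cytokines, 8 of 34 were higher (list alone, 14), among them Ccl8 (2.74) and Il1rn (2.45), which encodes a blocker of interleukin-1 signalling, with a mean of 0.93 (adjusted p = 7.59e-07; adjusted p = 0.191 with an estimated correlation). The interferon-induced list had 10 of 17 higher (list alone, 10), with Stat2 at 1.43 and Oas1a at 1.97 and a mean of 0.94 (adjusted p = 2.55e-06; adjusted p = 0.181 with an estimated correlation). Complement had 2 of 10 higher (list alone, 5), C3ar1, a receptor, at 2.85 and C1qa at 2.15 (list adjusted p = 0.00105; adjusted p = 0.118 with an estimated correlation).

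Antigen presentation had 1 of 7 members higher (adjusted over the list alone, 2), Cd74, the invariant chain of class II molecules, at 1.67 (list mean 0.70, camera adjusted p = 0.0225; adjusted p = 0.49 with an estimated correlation). The neutrophil list had 3 of 16 higher (list alone, 3), S100a9, S100a8 (2.07) and Ngp (1.59), with a mean of 0.60, and its mean was above 0 in 6 of 7 lines (camera adjusted p = 0.0451; adjusted p = 0.181 with an estimated correlation). In sgcb, the DS line with the highest S100a8 (5.17) and Ngp (4.63), Ibsp, a bone matrix gene, was 2.82 higher as well.

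The extracellular matrix list rose with 24 of 42 members higher and 0 lower (adjusted over the list alone, 28), a mean of 0.96 and 7 of 7 lines above 0 (limma's camera, adjusted p = 6.96e-14; adjusted p = 0.118 with an estimated correlation). Its members with the smallest p were Col14a1 (2.51 ± 0.33), Col5a2 (1.53), the proteoglycan gene Bgn (2.00) and the laminin gene Lamb1. Of the fibroblast list, 8 of 15 were higher (list alone, 10), including Col1a1 (1.95) and Col3a1 (1.69), the main fibrillar collagens, and Fap (1.60), with a mean of 0.97 (adjusted p = 2.51e-06; adjusted p = 0.118 with an estimated correlation). Among proteases and inhibitors 6 of 24 were higher and 1 lower (list alone, 9 and 2), led by Mmp2 (1.27) and Timp1 (2.98), with a mean of 0.68 (adjusted p = 0.0218; adjusted p = 0.379 with an estimated correlation).

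In the muscle regeneration list 11 of 31 members were higher (adjusted over the list alone, 18 higher and 1 lower), with Gadd45a at 1.94 and Vim, an intermediate filament of immature cells, at 2.26, beside Mest and H19, and a mean of 0.97 (limma's camera, adjusted p = 7.59e-07; adjusted p = 0.181 with an estimated correlation). Of the slow fibre genes 4 of 12 were higher (list alone, 5), Tnni1, Casq2 (2.28 ± 0.32), a calcium-binding protein of the sarcoplasmic reticulum, Atp2a2 (1.80) and Tnnt1 (2.10), with a mean of 0.95 (adjusted p = 0.0114; adjusted p = 0.427 with an estimated correlation). The list differed by more, 1.20, between bl10 and bl6, and against bl10 alone the 4 calls were lost, with Tnni1 at 2.58 (adjusted p = 0.135), Casq2 at 0.985 (0.35), Atp2a2 at 0.819 (0.495) and Tnnt1 at 0.92 (0.747). The cell cycle list had 3 of 39 higher (list alone, 5), Cks1b (2.22) and the replication genes Mcm3 (1.47) and Mcm4 (1.43), with a mean of 0.60 (adjusted p = 0.00494; adjusted p = 0.61 with an estimated correlation).

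Of the metabolic lists, 3 were lower by small amounts, each with a mean above 0 in 1 of 7 lines, sgcb (0.36, 0.303 and 0.558 in the order given), and the tricarboxylic acid cycle list was not called (mean -0.00605, adjusted p = 0.666, and adjusted p = 0.9 with an estimated correlation). Oxidative phosphorylation had 2 of 25 members lower (adjusted over the list alone, 2), the muscle forms Cox8b (-1.49 ± 0.30) and Cox7a1 (-1.10) of cytochrome c oxidase, with a mean of -0.32 and 6 of 25 members above 0 (limma's camera, adjusted p = 0.000797; adjusted p = 0.267 with an estimated correlation). Fatty acid oxidation had 1 of 22 lower (list alone, 0), Ech1 at -0.87, with a mean of -0.20 (adjusted p = 0.0114; adjusted p = 0.562 with an estimated correlation). Glycolysis had 1 of 21 lower (list alone, 1), Slc2a4, the insulin-regulated glucose transporter, at -1.49, with a mean of -0.21 (adjusted p = 0.0293; adjusted p = 0.61 with an estimated correlation). The other 21 lists, among them erythroid, adipocyte, endothelial, satellite cell, Schwann cell, tendon and ribosomal genes, had adjusted p from 0.0916 to 0.953. Dysf itself was higher in the DS lines (1.22 ± 0.35, limma adjusted p = 0.0358, 7 of 7 lines), as was Anxa1, an annexin, at 2.46 (0.00617).

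**Figure D3:**
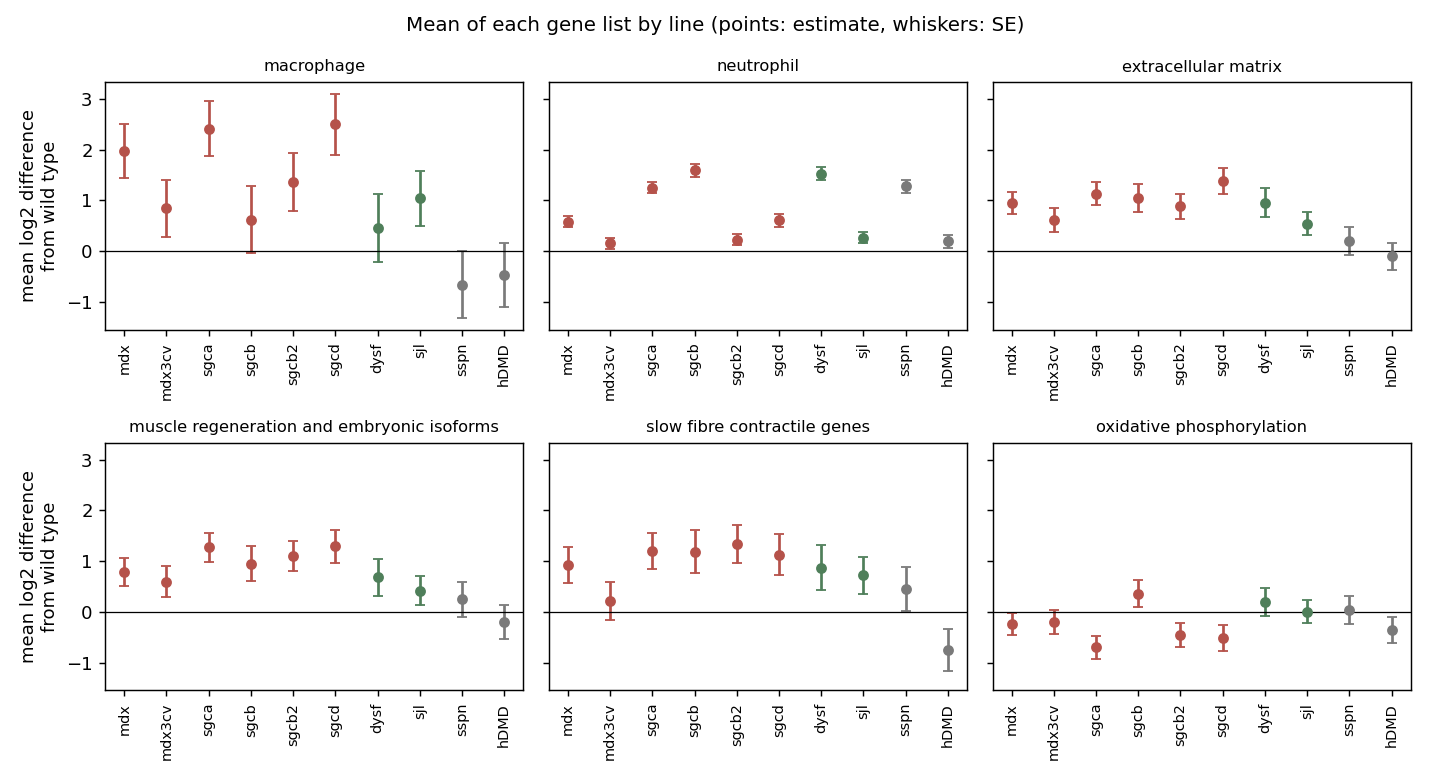
Mean log2 difference from wild type (y axes) of the genes of each list shown, in the lines shown (x axes), with points for the estimate and whiskers for 1 SE. The macrophage mean runs from 0.62 in sgcb to 2.50 in sgcd among the DS lines shown and is -0.67 in sspn and -0.48 in hDMD.

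Among single lines, sgca had the most genes, 485, but mdx had more without mdx sample 2 (462) or sgca sample 1 (289), and sgcd without bl6 sample 2 (159). In sgca, S100a9 rose by 6.49 ± 0.53 (limma adjusted p = 4.22e-07, n = 2), Clec7a by 5.62, Lgals3 by 5.23 and Ccl2 by 4.71. Below wild type, Sgca was joined by Cish (-3.13), Asb2 (-2.62) and Eya4 (-2.45). By limma, 391 genes were higher and 94 lower (80.6% higher), or 365 and 152 (70.6%) after the arrays were centred on their medians. The total was 799 against bl6 alone and 11 against bl10 alone. The 485 genes fell to 5 without sgca sample 1 and reached 874 without sgca sample 2. Without bl6 sample 2 they were 106, without mdx samples 1 and 2 they were 226 and 102, without bl10 samples 1 and 2 they were 184 and 314, without mdx3cv sample 2 they were 261 and without sjl sample 2 they were 794.

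In sgcd, 108 genes were higher and 31 lower by limma, with 240 genes in all against bl6 alone and 0 against bl10 alone. Lgals3 (5.85 ± 1.12, adjusted p = 0.0136), Clec7a (5.48), Ctss (5.13) and Gpnmb, a glycoprotein of macrophages (4.81), rose. Inmt (-3.45), Slc2a4 (-2.51), the phosphatidate phosphatase gene Lpin1 (-2.48) and Pttg1 (-2.47), which encodes securin, fell, the last by 4.65 against bl6 alone but at -0.281 against bl10 alone (adjusted p = 0.95). Leaving out 1 sample moved this count by over 1.5 times in 15 of 26 cases, down to 0 without sgcd sample 2 and up to 268 without sjl sample 1. In mdx, 80 genes were higher and 7 lower, with 262 genes in all against bl6 alone and 1 against bl10 alone. S100a9 (4.72 ± 0.52, limma adjusted p = 7.52e-05), Clec7a (4.44), Ctss (4.08) and Lgals3 (4.04) rose, and Cish (-3.23), Igfals (-2.33), Hspa1l (-2.16) and Ppp1r1a (-1.89) fell. This count moved in 21 of 26 cases, to 0 without mdx sample 1 and 462 without mdx sample 2.

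Genes of granulocytes led the rise in sgcb, as S100a9 did in sgca. S100a9 (6.06 ± 0.64, limma adjusted p = 3.76e-05), S100a8 (5.17), Ngp (4.63) and Hal, a histidine-degrading enzyme (3.72), rose, and 7 genes were higher and 0 lower, with 734 at an unadjusted p under 0.05. The median of all genes in this line was 0.17 and moved to 0.01 when the arrays were centred, with 5 genes higher. In sgcb2, 12 genes were higher and 1 lower. Xist, the RNA that silences the second X chromosome of females, rose by 4.75 ± 0.77 there (limma adjusted p = 0.0119), followed by Tnni1 (4.11), H19 (3.85) and Clec7a (3.68), while Arntl fell (-1.99). On single arrays Xist was at 4.33 and 6.26 in sgcb2 against mdx and sgcd. It was at -5.12 and -4.33 in bl10 and sgcd against sgcb2. The Y-linked genes Eif2s3y and Kdm5d were no lower than -0.475 and -0.417 in any DS line. The sex of the mice was not given, and a difference in sex between lines or samples is not excluded. Sex is therefore not separated from the missing protein in any comparison that holds sgcb2. Left-out samples moved these counts in 12 and 20 of 26 cases and took that of sgcb from 2 without sgcb sample 1 to 10 without bl6 sample 2, and that of sgcb2 from 0 without bl10 sample 1 to 45 without sgca sample 1.

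No gene passed limma's test in mdx3cv, where 566 genes had an unadjusted p under 0.05. The smallest adjusted p was 0.103. With array weights, 14 genes passed. Clec7a was 3.20 higher (adjusted p = 0.287). Leaving out 1 sample gave at most 1 gene (without bl6 sample 2 or hDMD sample 1).

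The DS lines resembled one another across genes. The log2 differences from wild type of the 21 pairs of DS lines correlated with a median r of 0.712 (0.409 to 0.902), against 0.333 for 20 simulated sets of unchanged groups that shared the same controls, and the covariance was 0.253 against 0.0655. With bl6 as the control of one line and bl10 of the other, the median r was 0.379 against 0.0429 and the covariance 0.177 against 0.00889. The closest pair was sgca and sgcd, which shared 99 higher genes, where independent lists would share 6.46, a number that leaves out the shared controls. DS lines with the dysferlin-deficient lines gave a median r of 0.477 against 0.328 simulated (14 pairs, 0.25 to 0.826, the highest for sgcb with dysf, covariance 0.164 against 0.0659), with sspn 0.215 against 0.331 (7 pairs, covariance 0.11 against 0.0822) and with hDMD 0.0419 against 0.325 (7 pairs, covariance 0.0135 against 0.0773). The pair of sgcb and dysf shared an array, and its own simulated r was 0.615, with a covariance of 0.324 against 0.168. With the controls split, the DS lines with sspn gave 0.0672 against 0.0844. The pair of dysf and sjl had r = 0.245 against 0.36. These values are across genes, which are not independent replicates, and they were described and not tested. The median r of the DS pairs was 0.518 without mdx sample 1.

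In the dysferlin-deficient lines (4 samples) the genes past the test were few. S100a9 rose by 3.75 ± 0.49, Csnk1e, a kinase of the circadian clock, by 2.68 ± 0.35 and Ctse, an aspartic protease of immune cells, by 2.35 ± 0.38 (limma adjusted p = 0.000733, 0.000733 and 0.00964), each in 2 of 2 lines. By limma 3 genes were higher and 0 lower, against 574 at an unadjusted p under 0.05. The count was 8 with the arrays taken as independent, 5 with array weights and 16 without bl6 sample 2, and 10 of the 26 left-out samples moved it. The median of all genes was 0.12 and moved to 0.00 with centred arrays.

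With limma's camera 8 lists were higher in the dysferlin-deficient lines. The neutrophil list (mean 0.90, 1 of 16 members higher; adjusted over the list alone, 5) had adjusted p = 6.33e-05, and adjusted p = 0.0091 with an estimated correlation. The extracellular matrix list had 0 of 42 members past the test over all genes and 13 adjusted over the list alone, with Col14a1 at 1.62 and Bgn at 1.40 and a mean of 0.75 (adjusted p = 8.79e-10; adjusted p = 0.298 with an estimated correlation). The fibroblast list had 0 of 15 (list alone, 5; mean 0.81; adjusted p = 0.000114, and adjusted p = 0.298 with an estimated correlation). Adipocyte genes had 0 of 12 (list alone, 3), with Ucp1, the uncoupling protein of brown fat, at 3.43 and Fabp4, a fatty acid carrier, at 1.85 (adjusted p = 0.000829; adjusted p = 0.449 with an estimated correlation). Tendon (list alone, 3; adjusted p = 0.00366, and adjusted p = 0.449 with an estimated correlation), macrophage (list alone, 1; 0.00368, and adjusted p = 0.801 with an estimated correlation), slow fibre (list alone, 3; 0.0122, and adjusted p = 0.472 with an estimated correlation) and regeneration genes (list alone, 1; 0.0129, and adjusted p = 0.757 with an estimated correlation) had 0 members each past the test over all genes. The tendon mean was 1.74 ± 0.504 in dysf and 0.0881 ± 0.41 in sjl, and the neutrophil mean 1.53 and 0.268.

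The lines dysf and sjl differed. The labels did not give their background strains, so a difference in background cannot be told apart here from an effect of the mutation. In dysf the granulocyte genes S100a9 (5.36 ± 0.65, limma adjusted p = 0.000425), S100a8 (5.27) and Ngp (3.86) rose with Ibsp (3.34), a protein of bone matrix, among 7 higher and 0 lower genes, with 553 at an unadjusted p under 0.05. In sjl, Tfb2m, a mitochondrial transcription factor (3.48), Csnk1e (2.94), the transcription factor Sp1 (2.43) and Scoc (2.21) rose, and the sialidase gene Neu2 (-3.26), Pttg1 (-2.91) and Rab6a (-1.57), a GTPase of the Golgi, fell, among 13 higher and 3 lower genes. Pttg1 in sjl was at -5.10 against bl6 alone and -0.731 against bl10 alone (adjusted p = 0.999). Tested against each other by limma, dysf was higher than sjl in S100a8 (4.94), Pttg1 (4.51), Ngp (3.83) and Ibsp (3.05) and lower in Tfb2m (-3.17) and Zfp458 (-2.47), among 8 higher and 2 lower genes (adjusted p from 0.0121). These 10 genes became 0 without dysf sample 2 and 32 without sgcb sample 1, and 16 of 26 left-out samples moved the count. For dysf and sjl 6 and 18 of 26 did so, and the counts ranged from 1 (without bl10 sample 2) to 17 (without dysf sample 1), and from 2 (without bl10 sample 1) to 26 (without mdx sample 1). The median of all genes in dysf, 0.15, moved to 0.00 with centred arrays.

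The DS and dysferlin-deficient lines were also compared directly. Mest (2.39 ± 0.46, limma adjusted p = 0.0397) and Casq2 (1.96 ± 0.33, 0.0206) were higher in the DS lines. Ucp1 (-4.48 ± 0.81, adjusted p = 0.0241), Csnk1e (-1.71), Tfb2m (-1.68) and Rbp7 (-1.66), a retinol-binding protein, were lower, so that 2 genes were higher and 6 lower. With dysf alone as the dysferlin-deficient line, Tfb2m was at -0.0941 (adjusted p = 0.967) and Csnk1e at -1.45 (0.176). The count was 0 without a dye term, and 19 of 26 left-out samples moved it, from 0 without sgcd sample 2 to 25 without sgca sample 2. By camera 13 lists differed, 6 higher and 7 lower in the DS lines, and all 13 calls were lost with an estimated correlation. The macrophage list was higher by a mean of 0.87 with 0 of 41 members past the test (adjusted over the list alone, 10; adjusted p = 3.77e-13, and adjusted p = 0.209 with an estimated correlation). The adipocyte list was lower by -1.35 with 1 of 12 members lower (list alone, 7; adjusted p = 1.05e-10, and adjusted p = 0.16 with an estimated correlation). Interferon-induced genes (0.60; list alone, 6 of 17) and chemokines (0.57; list alone, 4 higher and 1 lower of 34) were higher, both with adjusted p = 0.209 with an estimated correlation, and oxidative phosphorylation was lower (-0.42, list alone 0 of 25, adjusted p = 3.03e-05; adjusted p = 0.209 with an estimated correlation).

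Between the dystrophin- and the sarcoglycan-deficient lines, Csrp3, a protein of the Z-disc that responds to stretch, was the gene that passed limma's test, at -2.11 ± 0.35 in the dystrophin-deficient lines (4 samples against 10, adjusted p = 0.0371). No gene was higher, and 137 genes had an unadjusted p under 0.05. The call was lost in 18 of the 26 fits with 1 sample left out, for example without bl10 sample 2, and the count was 7 with array weights. Of the lists, 2 were higher and 6 lower by camera, and all 8 calls were lost with an estimated correlation. Regeneration genes (mean -0.38, 1 of 31 lower; adjusted over the list alone, 2; adjusted p = 0.000297, and adjusted p = 0.663 with an estimated correlation), cell cycle genes (-0.39, 0 of 39, list alone 0; adjusted p = 0.000297, and adjusted p = 0.663 with an estimated correlation) and matrix genes (-0.25, 0 of 42, list alone 0; adjusted p = 0.00176, and adjusted p = 0.693 with an estimated correlation) were lower. Within the protein classes, mdx was higher than mdx3cv in S100a9 (4.22 ± 0.61, limma adjusted p = 0.00582), the gene that passed there, and sgcb was higher than sgcb2 in Ngp (4.05 ± 0.64, 0.0228), while Xist was at -4.49 there without passing (adjusted p = 0.137). These single calls became 0 without mdx sample 1 and without sgcb sample 1, and reached 22 without mdx sample 2 and 7 without bl6 sample 1, and 5 and 18 of the 26 left-out samples moved them.

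In the sarcospan-deficient line, granulocyte genes rose with a gene of bone. S100a9 rose by 4.47 ± 0.64, Ibsp by 3.57 ± 0.54, Ngp by 3.38 ± 0.59 and Pdzrn3, a ubiquitin ligase of the neuromuscular junction, by 2.97 ± 0.58 (limma adjusted p = 0.005, 0.00596, 0.028 and 0.0449, n = 2). Camp (2.61), an antimicrobial peptide of neutrophils, Trpm7 (2.38) and Cd1d1 (2.19) completed the 7 higher genes, and were named after their values were seen. By limma 0 genes were lower, and 790 had an unadjusted p under 0.05. The count was 0 with arrays centred and scaled alike, 193 with array weights, 0 without sspn sample 2 and 43 without sgca sample 1, and 21 of 26 left-out samples moved it.

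Of the lists, 5 were higher and 2 lower in sspn by limma's camera. The neutrophil list (mean 1.28, 3 of 16 higher; adjusted over the list alone, 5) had adjusted p = 1.39e-05 and adjusted p = 0.00419 with an estimated correlation. The macrophage list was lower than in wild type (mean -0.67, 0 of 41 lower, list alone 0; adjusted p = 0.000194, and adjusted p = 0.885 with an estimated correlation), as were ribosomal protein genes (-0.51, 0 of 39, list alone 0; adjusted p = 1.39e-05, and adjusted p = 0.885 with an estimated correlation). Adipocyte (1.64, 0 of 12; list alone, 4), fast fibre (1.17, 0 of 11; list alone, 0), glycolysis (0.65, 0 of 21; list alone, 0) and tricarboxylic acid cycle genes (0.86, 0 of 17; list alone, 0) were higher, all 4 with adjusted p = 0.885 with an estimated correlation.

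In hDMD, Rab6a was lower by -2.24 ± 0.32 (limma adjusted p = 0.00416, n = 2), and no gene was higher, with 429 genes at an unadjusted p under 0.05. The slow fibre list was lower (mean -0.75, 0 of 12; adjusted over the list alone, 4; adjusted p = 0.00552, and adjusted p = 0.963 with an estimated correlation), as was the tricarboxylic acid cycle list (-0.60, 0 of 17; list alone, 0; adjusted p = 0.0262, and adjusted p = 0.963 with an estimated correlation). The median of all genes, 0.05, moved to -0.11 with centred arrays. The count was 5 against bl10 alone, 0 without bl10 sample 2, bl6 sample 1 or sgcd sample 2 and 275 without hDMD sample 2, and 11 of 26 left-out samples moved it.

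The wild type strains differed in Pttg1, a regulator of chromosome separation, which was lower in bl10 than in bl6 by -4.37 ± 0.62 (limma adjusted p = 0.00478, 2 samples each). No gene was higher, and 522 genes had an unadjusted p under 0.05. The count was 18 with array weights and 0 without either sample of bl10 or of bl6 or without mdx3cv sample 2, and 2 without either sample of mdx. Slow fibre genes were higher in bl10 (mean 1.20, 0 of 12; adjusted over the list alone, 5; camera adjusted p = 9.22e-05, and adjusted p = 0.807 with an estimated correlation), as were macrophage (0.73, 0 of 41; list alone, 0), matrix (0.44, 0 of 42; list alone, 2), interferon-induced (0.64, 0 of 17; list alone, 1), chemokine (0.56, 0 of 34; list alone, 1) and endothelial genes (0.48, 0 of 15; list alone, 3), all 5 with adjusted p = 0.844 with an estimated correlation. Sample 2 of bl10 was at 1.91 from the wild type median for slow fibre genes and 1.17 for macrophage genes, against 0.241 and -0.0713 in bl10 sample 1.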

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

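The tests of the 3 explained patterns (mixed or mislabelled bl10 sample, compressed ratios, strain difference, blood, bone and marrow, and time of sampling) were chosen after the results had been seen, as were the choices of whole groups, and the counts of other splits of the samples were planned.

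Outlying samples were sought in 60 groups of list means, of which 3 had one, where chance gives about 1 in 20. In the dysferlin samples, sjl sample 1 was highest for the fibroblast list, with a gap of 0.876 of the range, and for the muscle regeneration list, with 0.833. In the wild type samples, bl10 sample 2 was highest for the muscle regeneration list (gap 0.873 of the range, 0.88 on the log2 scale above the median). Values of single samples come from a loop with as many arrays as samples, in which errors add up along the loop.

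Differences between groups of one kind passed limma's test of the difference for 8 genes between the DS and the dysferlin-deficient lines, 10 between dysf and sjl, and 1 each between dystrophin- and sarcoglycan-deficient lines, mdx and mdx3cv, and sgcb and sgcb2. Gene lists differed by camera in 13 and 8 cases in the first and the third of these, none of them with an estimated correlation. Of 2754 rows with no single gene name, which no comparison used, 34 differed between the DS lines and wild type by limma (22 higher), or 1.23%, against 4.78% of the rows with 1 gene.

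The macrophage list was less raised on the 3 arrays that set a DS line against bl10 (0.62, 0.62 and 0.64) than on the 2 against bl6 (3.72 and 2.96), but these arrays carried other lines. A mixed or mislabelled bl10 sample 2 stays open, because without that sample bl10 minus bl6 was 0.53 ± 0.74. This test replaced an earlier one, the value of 0.62 on the array of bl10 sample 1, after that had decided nothing. That value was as low as those on the arrays of bl10 sample 2 (0.621 and 0.641), so the low means were not confined to sample 2. It rests on 1 array, which carried sgcb2. Compression of the ratios on the bl10 arrays could account for a part, as the SD of uncalled genes there was 0.64 of that on the bl6 arrays, but the macrophage mean was 0.188 of it. A true strain difference, the biological explanation, gave 0.73 ± 0.60 for bl10 minus bl6, so the 3, and the difference in lines, cannot be told apart with 2 samples per strain.

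S100a8, S100a9 and Ngp were higher in sspn, sgcb and dysf, by a mean of 4.62 ± 0.51 over these lines, and also in sgca (4.60 ± 0.49, with Ibsp at 2.54) and sgcd (2.38 ± 0.545, with Ibsp at 1.62), and with Ibsp near wild type in mdx (2.77 ± 0.479) and sgcb2 (1.40 ± 0.513). The lines sspn, sgcb and dysf shared arrays with one another, and none of them shared an array with bl6 or bl10. They were compared with wild type only through other samples, so errors along the loop may be common to them. Their agreement, also in the bone, marrow, adipocyte and tendon lists below, is therefore not that of 3 independent lines. The erythroid list had a mean of 0.338 ± 0.219 over sspn, sgcb and dysf. In sspn (0.163 ± 0.253) and sgcb (0.182 ± 0.252) it was within 2 SE of wild type. S100a8, S100a9 and Ngp had means of 3.73 and 5.29 there. This argues against blood left in the samples as the source of a rise of that size in sspn and sgcb. A smaller share of blood is not excluded, as the list holds 7 genes and its errors are wide. In dysf the erythroid list stood at 0.669 ± 0.258, over 2 SE above wild type, so blood stays open there. A candidate source is RNA of bone and marrow, as a bone list without Ibsp was 0.368 ± 0.137 higher (14 genes; 0.244 ± 0.111 with centred arrays; Ibsp itself 3.24) and a marrow list without the 3 genes 0.639 ± 0.129 (19 genes, of which 12 are also in the neutrophil list), both written after the pattern was seen. Against it stand the bone list in sgca (0.21 ± 0.131) and sgcd (0.00558 ± 0.146), the osteocyte genes Dmp1 (-0.92, -0.88 and -0.93 in sspn, sgcb and dysf) and Phex (-0.52, -0.74 and -0.63), the low marrow gene Elane (0.46, 0.14 and 0.17), mdx, with S100a9 at 4.72 and Ibsp at -0.03, and the adipocyte (1.64, 1.15 and 1.45) and tendon lists (0.856, 1.32 and 1.74), which stood further above wild type than the bone list did. RNA of fat or tendon, at -0.359 and 0.357 for these lists in sgca, and an entry of neutrophils into the tissue stay open and were not tested.

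Arntl was lower in the DS lines, and may have followed the time of day at which the mice were sampled. Clock genes of the opposite phase minus those of the phase of Arntl, without Arntl, stood 0.565 ± 0.206 above wild type, as a difference in time would give. The genes of its own phase were at -0.0357 ± 0.17, the partners Clock (0.39) and Npas2 (0.37) were not lower, and bl10 and bl6 differed in the same measure by -0.84 ± 0.33. Arntl was also lower in sspn (-1.80) and hDMD (-1.73), without passing the test in either, but not in sjl (0.01). An effect of the missing proteins on the clock stays open and was not tested.

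Other splits of the same samples were counted with each class fitted as 1 group, which gave 483 genes for DS against wild type in place of 510. Of 100 splits 2 gave as many, the real one included, so few splits that broke up the lines reached the count. The highest other, 649, had bl6 samples 1 and 2, mdx sample 2 and sgcb sample 2 as its second class, and so held a part of the real comparison. With both samples of a group kept together, 1 of 36 choices of 2 groups gave as many, the real one. The highest other was 410 (sgcb with bl6), which kept bl6 and put a DS line in the place of bl10. With bl10 as the only control the count was 10. The count may thus follow bl6, and the rank among choices that overlap does not exclude chance. For DS against dysferlin-deficient lines 3 of 100 splits gave as many as the real 2 (highest other 89, many times the real count, which points to a structure of the samples), but so did 3 of 36 choices of whole groups (highest other 275, sgcb with dysf), so chance was not excluded for whole lines.

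For dysferlin-deficient lines against wild type 3 of 35 splits gave as many as the real 1 (highest other 3), so chance was not excluded. For dystrophin- against sarcoglycan-deficient lines the real count by limma was 0, with 143 genes at an unadjusted p under 0.05, so that 100 of 100 splits had to give as many and the count tests nothing. The highest other split there gave 666, which points to a structure of the samples.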

How the results depend on the processing

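Array weights and block centring were chosen after the data were seen, and the other alternatives were planned. The filter alternatives removed no gene, since no value was missing, and say nothing about stability. Of 154 gene results 146 passed the test, 0 of these changed sign in an alternative, and 9 kept their call in every one of up to 40 alternatives: Clec7a and S100a9 in the DS lines, Csnk1e in the dysferlin-deficient lines and in sjl, S100a9 in sgca, sgcb and dysf, Ngp in sgcb, and Sgca in sgca. Spot brightness against background was not given in the values used here, so its limit on single genes is unknown. The test was limma throughout. Where an alternative with all samples called 0 genes, 130 to 893 genes had an unadjusted p under 0.05. With each row on its own these were 311 to 1241 rows. Except where fewer samples or an estimated correlation were used, the cause of a change was not tested.

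Counts of genes are given in the order of the comparisons named. With the arrays taken as independent they were 8 in dysferlin-deficient lines, 16 in sspn, 2 in hDMD, 738 in sgca, 36 in sgcb2, 260 in sgcd, 14 in dysf, 37 in sjl, 6 for sgcb against sgcb2 and 22 for dysf against sjl. Without a dye term they were 293 in DS lines (all 293 shared with the 510), 3 in sspn, 0 in hDMD, 0 for dystrophin against sarcoglycan, 0 for DS against dysferlin, 30 in mdx, 306 in sgca, 4 in sgcb, 64 in sgcd and 2 in sjl.

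With arrays centred and scaled alike they were 180 in DS lines (179 shared), 1 in dysferlin-deficient lines, 0 in sspn, 2 for bl10 against bl6, 2 in mdx, 194 in sgca, 4 in sgcb, 3 in dysf, 5 in sjl, 0 for mdx against mdx3cv, 0 for sgcb against sgcb2 and 6 for dysf against sjl. With centring alone sjl had 10. With block centring hDMD had 2, mdx3cv 1 and sgcb against sgcb2 2.

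Against bl6 alone the counts were 7 in dysferlin-deficient lines, 262 in mdx, 799 in sgca, 240 in sgcd and 40 in sjl. Against bl10 alone they were 10 in DS lines (all 10 among the 510, and 1 of the 510 changed sign), 3 in sspn, 5 in hDMD, 1 in mdx, 11 in sgca, 3 in sgcb2, 0 in sgcd and 2 in sjl. With dysf alone the dysferlin comparison had 7. With each row on its own the counts, of rows, were 2 in hDMD, 0 for dystrophin against sarcoglycan, 2 for bl10 against bl6, 785 in sgca, 234 in sgcd, 3 for mdx against mdx3cv and 5 for sgcb against sgcb2.

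With array weights the counts were 5 in dysferlin-deficient lines, 193 in sspn, 7 for dystrophin against sarcoglycan, 4 for DS against dysferlin, 18 for bl10 against bl6, 45 in mdx, 14 in mdx3cv, 1157 in sgca, 12 in sgcb, 90 in sgcb2, 317 in sgcd, 10 in sjl, 11 for sgcb against sgcb2 and 25 for dysf against sjl.

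The replicate numbers did not pair the samples: over 78 pairs of groups the deviations correlated from -0.796 to 0.663 (median -0.0338). With the replicate number as a block, sspn had 4 genes, sgcb against sgcb2 had 2 and dysf against sjl had 3. In DS lines 524 genes passed, 486 of them shared, and no other count moved by over 1.5 times.

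Gene lists called with an estimated correlation were 0 in DS lines, 1 in dysferlin-deficient lines, 1 in sspn, 0 in hDMD, 0 for dystrophin against sarcoglycan, 0 for DS against dysferlin and 0 for bl10 against bl6. In hDMD 1 list was called with centring, 1 with centring and scaling and 1 with block centring. For bl10 against bl6, 2 lists were called with centring and scaling and 3 with array weights, and 5 in dysferlin-deficient lines with array weights.

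With each sample left out in turn, the counts ran from 74 to 679 in DS lines, 2 to 16 in dysferlin-deficient lines, 0 to 43 in sspn, 0 to 275 in hDMD, 0 to 1 for dystrophin against sarcoglycan, 0 to 25 for DS against dysferlin, 0 to 2 for bl10 against bl6, 0 to 462 in mdx, 0 to 1 in mdx3cv, 5 to 874 in sgca, 2 to 10 in sgcb, 0 to 45 in sgcb2, 0 to 268 in sgcd, 1 to 17 in dysf, 2 to 26 in sjl, 0 to 22 for mdx against mdx3cv, 0 to 7 for sgcb against sgcb2 and 0 to 32 for dysf against sjl. The sample that stays in a group is then assumed to vary like the other groups. The median correlation of DS lines ran from 0.518 (without mdx sample 1) to 0.766, and the number of missing genes lower in their own line at an unadjusted p under 0.05 ran from 1 (without sspn sample 2) to 5 (without dysf sample 1 or sgcb sample 1), around 3.

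Missing genes changed sign where they had not passed the test. Dmd in mdx3cv was 0.0213 without bl6 sample 1 and -0.702 without mdx3cv sample 2. Sgcb in sgcb was 0.12 without sgcb sample 2 and -2.48 without sgcb sample 1. Dysf in sjl was -0.37 without sjl sample 1 and 2.14 without sjl sample 2. Sgcd in sgcd was 0.00478 against bl10 alone, 0.17 without sgca sample 2, 0.43 without sgcd sample 1 and -0.962 without sgcd sample 2.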

Other observations

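The lists of heat shock and chaperone genes and of fibrogenic growth factors were fixed with the others, and the correlations between arrays were looked at after the results had been seen.

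Chaperones went both ways in the DS lines. Hsp90b1, a chaperone of the endoplasmic reticulum, rose by 1.61 ± 0.33 (limma adjusted p = 0.00585, 14 samples against 4), Dnaja1, a partner of Hsp70, by 1.28, and Hspd1, which folds proteins in mitochondria, by 1.09, while Hspe1, which forms a complex with Hspd1, fell (-0.82). Of 16 chaperone genes 3 were higher and 1 lower, and the list of heat shock and chaperone genes was not called by camera (mean 0.35, adjusted p = 0.418, and adjusted p = 0.677 with an estimated correlation).

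Of 25 genes of TGF-beta and fibrogenic growth factors, 4 were higher in the DS lines and 1 lower. Ccn2, a matrix-associated protein that TGF-beta induces, rose by 1.34 ± 0.33 (limma adjusted p = 0.0169), as did Tgfbi (1.06) and Fst (0.67), which binds activins, and the activin gene Inhba fell (-1.27). The list of TGF-beta and fibrogenic growth factors was not called by camera (mean 0.31, adjusted p = 0.0916, and adjusted p = 0.542 with an estimated correlation).

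Each RNA sample lay in channel 1 of one array and channel 2 of another, so that the values of the 2 arrays correlate below 0 where the sample sets the ratios. The correlation was above 0 for sgca sample 2 (0.471), dysf sample 1 (0.298), sgcb2 sample 1 (0.173) and mdx3cv sample 2 (0.0985) and below 0 for the remaining samples.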
